A study of Mus musculus with 6 samples.

How the data were processed

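RNA was measured in 6 samples of subcutaneous tumours grown in nude mice, which lack a thymus and so most mature T cells. The tumours came from injected spleen cells of diseased mice carrying a doxycycline-repressible miR-155 transgene, in which doxycycline (DOX) turns the microRNA off. In 3 samples the mice had received DOX in chow (2.3 mg per kg) for 16 hours before harvest, and in 3 they had not. Per the labels' protocols, tumours were dispersed to single cells, red blood cells were lysed, and libraries were made from total RNA after ribosomal RNA depletion.

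Per the submitters' processing notes, RSEM, DESeq and the mouse build mm9 were used, with no version given. The deposited file is a table of the authors' comparison of both groups. Its fold change column is a linear ratio, per the file headers, and the authors' unadjusted and adjusted p-values stand beside it. It holds no value per sample, no group mean, no standard error and no depth, so the precision of a single sample is unknown and no test across samples was run here. The smaller a gene's adjusted p, the larger its difference against the spread between samples as the authors' tool modelled it. The labels do not say that the samples of a group came from separate animals, so these p-values measure only the spread between these samples, which may be technical.

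The numerator of the fold is not given in the sources used here. All folds were read as DOX over no DOX, a reading fixed before the data were examined, and every direction below turns if the authors divided the other way. Log2 folds were taken from the deposited ratio, because the deposited log2 column has 579 cells that are not numbers, where the ratio is 0. Of 29209 genes and transcripts in the table, 18543 have an adjusted p and form the tested set. The authors' adjusted p-values equal a Benjamini-Hochberg adjustment over those 18543, with a largest difference of 2.09e-06. Of the tested set, 15784 have a finite fold. For 2180 the deposited ratio is Inf and for 579 it is 0, and no fold is printed for these. The table has 26 identifiers that a spreadsheet turned into dates, and 23 of them were tested. They are not named here.

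Tested identifiers were matched to current mouse symbols by symbol (11743), RefSeq accession (1405) or a unique synonym (2022), and 3373 had no match. Some genes stand in the table more than once, and 1349 tested entries share a current symbol with another. Histone and ribosomal protein genes have near-identical copies, so the division of reads among them is uncertain. The build of the annotation used here, GENCODE release M21, is GRCm38 and not mm9, so it served for transcript sequence, length and GC alone and no coordinates are given. For each gene the longest protein-coding transcript and the longest annotated 3' UTR were used.

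A gene was called at the authors' adjusted p under 0.05. The 36 gene lists were fixed before the data were examined. For each, calls in each direction were counted, and a two-sided Fisher exact test set them against all other tested genes, with Benjamini-Hochberg adjustment over 72 tests. Calls adjusted over the list alone were counted beside them. A list's median log2 fold over members with a finite fold was placed among 10000 random lists of the same size, for lists with at least 5 such members. Fisher tests and percentiles are across genes, which are not independent replicates. The planned matching of random lists on mean expression needs group means. Unmatched random lists therefore took its place, and 2 substitutes chosen after seeing the data matched on transcript length and GC or on implied spread. Implied spread is the absolute log2 fold over the normal quantile of the unadjusted p, for p up to 0.9. It is built from the fold and p themselves, so matching on it partly conditions on the values under test. Percentiles from this matching are therefore limited support.

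Genes with a miR-155 seed match in the 3' UTR (7mer-m8 AGCATTA or 7mer-A1 GCATTAA) were set against random genes without one, matched on 3' UTR length and implied spread, the latter in place of mean expression. The same was done for 6 shuffled 7-mers. The named genes follow a rule set in advance: the 10 largest rises and falls past the threshold, the 5 smallest adjusted p in each direction, up to 4 called members per list by adjusted p, and 6 reported miR-155 targets. The rule's minimum on mean expression could not be applied, and a finite fold was required instead. Clone-named and predicted genes were passed over, 353 of those that rose and 66 of those that fell. Of the genes the rule names, 1 is not reported here. The transcripts of miR-155 itself and its host gene are not analysed here.

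The list and seed procedures were tested on simulated data made by dealing the table's entries to genes at random. In 20 deals, 0 of 1440 list tests over 18543 genes were called. Lists of 20 with 8 fallen members passed in 200 of 200 cases, and lists with 4 fallen members in 0 of 200. All cases with the same number of fallen members share the same Fisher counts, so these are not recovery rates. They show only that a list with few changed members can be missed. A shift of 0.25 planted on the seed match among 12619 genes ranked 1 among all 7-mers in each of 5 runs. Dealing at random also removes the link of fold with transcript length and GC that the real table has. These runs therefore do not tell how often a list or 7-mer without a signal stands out in the real data. Alternatives covered the threshold, the adjustment, a minimum fold, recentring, the genes tested, the matching of random lists, shared list members and the seed definition. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.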

Results

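Tumours with and without 16 hours of miR-155 withdrawal were compared, 3 samples in each group, to ask which transcripts change when an overexpressed microRNA is turned off. No tumour without the transgene received DOX, so effects of DOX itself cannot be told apart from those of miR-155 loss. The loss of miR-155 was not checked here. The authors' deposited table gives a fold and p-values per gene. Sequencing depth per sample is unknown. Folds are read as DOX over no DOX, and the table does not state this order. If it is reversed, "rose" and "fell" exchange places throughout.

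Kit, the receptor for stem cell factor, the tyrosine kinase gene Src and the proto-oncogene Myc fell with the smallest adjusted p. Their log2 folds in the authors' deposited table were -4.25 (adjusted p = 1.76e-23), -4.60 (1.19e-21) and -4.80 (4.34e-21). Emid1 (-4.67) and the cytokine gene Mif (-3.56) followed in the authors' deposited table. Among genes that rose, clone-named and predicted ones aside, the smallest adjusted p in the authors' deposited table belonged to Pol, listed as a LINE-1 sequence (2.81, 3.48e-12), to Zfp353 (3.00) and to Fgd4 (2.56). The cohesin loader gene Nipbl (2.47) and Ankrd12 (2.89) came next in the authors' deposited table. In all, 2101 of 18543 tested genes passed, 1060 higher and 1041 lower, and 4147 had an unadjusted p under 0.05 in the authors' deposited table. Of the genes past it, 353 of the higher and 66 of the lower were clone-named or predicted, and with only protein-coding matches tested 781 were higher and 1027 lower. Of those past the threshold, 1054 of the higher and 1008 of the lower changed at least 2-fold. The median log2 fold was 2.08 among the genes that rose with a finite fold and -1.55 among those that fell. Over all tested genes with a finite fold the median was 0.17. A Bonferroni adjustment left 137 higher and 154 lower, and an adjusted p under 0.01 left 576 and 569.

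**Figure D1:**
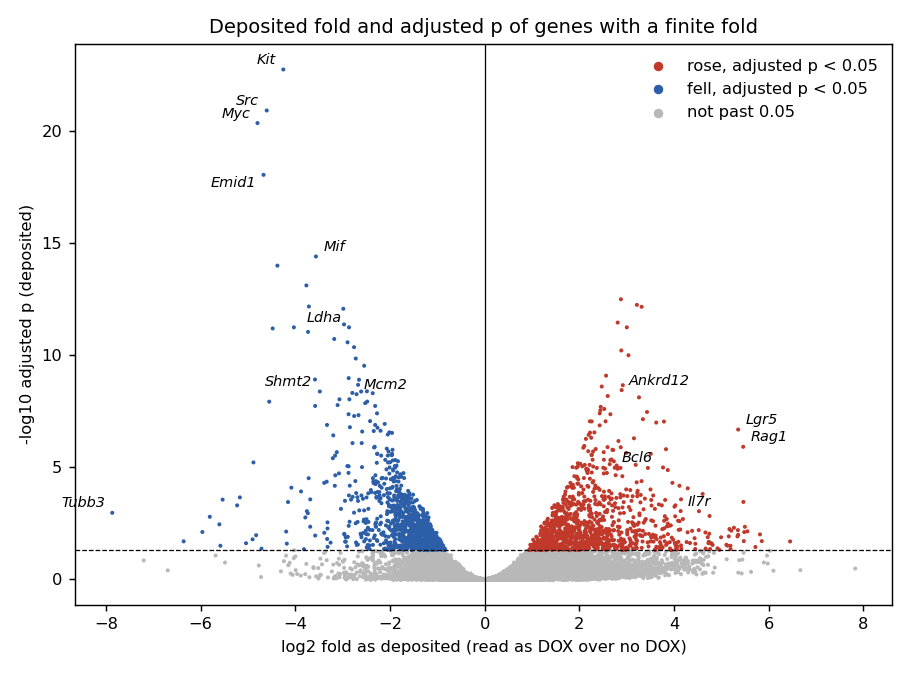
Log2 fold read as DOX over no DOX (horizontal) against -log10 of the adjusted p (vertical) for the 15784 tested genes with a finite fold, both from the authors' deposited table, with the dashed line at 0.05. Red points rose, blue points fell, and Kit, Src and Myc stand highest.

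Among genes past the threshold with a gene name and a finite fold, the largest rises included the interferon-induced genes Rsad2, Ifi202b and Mx1, at log2 folds of 5.85, 5.72 and 5.47 in the authors' deposited table. Rag1, which encodes part of the V(D)J recombinase, reached 5.46, and Lgr5, a receptor for R-spondins, 5.35 in the authors' deposited table. Raph1 (5.82), the zinc finger gene Zfp521 (5.55), Kcnrg (5.50), the imprinted gene Peg3 (5.48) and Clec7a, the beta-glucan receptor of myeloid cells (5.34), complete these 10 in the authors' deposited table. The tubulin genes Tubb3 (-7.87) and Tuba8 (-5.81) were among the largest falls in the authors' deposited table. So were Mylc2pl (-6.36), Tnfsf11, the gene of RANK ligand (-5.96), Camkv (-5.60), Camkk1 (-5.53) and Car12 (-5.23) in the authors' deposited table. Ggnbp1 (-5.17), Plch2 (-4.90) and Pglyrp2 (-4.88) complete the falls in the authors' deposited table. Adjusted p-values of these 20 in the authors' deposited table reached 0.0361, for Ifi202b, so the most extreme folds are not the most secure.

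Genes of growth fell as groups. In the MYC and ribosome biogenesis list, 20 of 25 tested members fell and 0 rose (Fisher exact adjusted p = 2.38e-19), and 23 fell and 1 rose when adjusted over the list alone. Besides Myc these included the rRNA processing gene Fbl (-2.87), Nolc1 (-2.28) and the RNA polymerase I gene Polr1a, listed as Rpo1-4 (-1.98), in the authors' deposited table. Of 18 glycolysis genes 13 fell and 0 rose (8.09e-12), 14 adjusted over the list alone. Ldha (-2.86), Tpi1 (-2.26), Pkm2 (-2.05) and Gapdh (-1.96) led by adjusted p in the authors' deposited table. Of 18 cholesterol synthesis genes 12 fell and 0 rose (2.25e-10), and 17 adjusted over the list alone. Those that fell included Cyp51 (-2.87), Fdps (-2.85) and the sterol regulator gene Srebf2 (-2.31) in the authors' deposited table. The medians of these 3 lists were -1.62, -1.77 and -2.10, each at percentile 0 of random lists.

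Proliferation genes fell too. In the same comparison macrophage markers had a median of 2.16 and fibroblast markers of 1.86, while B lineage markers had one of -0.07, from the authors' deposited table, and the growth genes above moved beside the same markers. Of 28 S phase and DNA replication genes 18 fell and 0 rose (Fisher exact adjusted p = 7.37e-15), and 24 fell adjusted over the list alone. Mcm2, of the replicative helicase (-2.71), Rrm1 (-1.95), Pcna (-1.94) and Rrm2 (-1.70) led in the authors' deposited table. Of 26 mitosis genes 11 fell and 0 rose (7.04e-07), 15 adjusted over the list alone. Plk1 (-1.61), Aurkb (-1.57), Kif20a (-1.34) and Cdk1, listed as Cdc2a (-1.28), led in the authors' deposited table. Of 15 histone genes 10 fell and 0 rose (9.96e-09), 14 adjusted over the list alone. Hist1h2ae (-1.91), Hist1h1b (-1.89), Hist1h2ab (-1.78) and Hist1h3b (-1.43) led in the authors' deposited table, with reads that near-identical copies can share.

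Of the stress response lists, the unfolded protein and integrated stress response passed the Fisher test for falls, and heat shock and hypoxia did not. Of 16 unfolded protein response genes 7 fell and 1 rose (Fisher exact adjusted p for the falls = 0.000130), 8 and 1 adjusted over the list alone. The endoplasmic reticulum chaperone gene Calr (-2.01), Manf, listed as Armet (-1.61), Pdia6 (-1.38) and Pdia4 (-1.31) led in the authors' deposited table. Of 20 integrated stress response genes 5 fell and 0 rose (0.0276), 5 and 1 adjusted over the list alone. The members Shmt2 (-3.48), Slc7a5 (-3.39), Phgdh (-2.30) and Psat1 (-2.07), named from the authors' deposited table, serve serine and glycine synthesis or amino acid uptake. That list's call ended at a threshold of 0.1 (Fisher exact adjusted p = 0.0667). Of 13 heat shock genes 3 fell, 3 adjusted over the list alone, namely Hsp90ab1 (-2.61), Hspd1 (-2.22) and Hspe1 (-2.05) in the authors' deposited table, and the list did not pass (0.170). Of 16 hypoxia genes 2 fell, 2 adjusted over the list alone, Vegfa (-2.39) and the glucose transporter gene Slc2a1 (-1.49) in the authors' deposited table (list 0.738). The medians of heat shock (-0.72, percentile 1.06) and hypoxia (-0.68, 0.72) genes lay below the central 95% of random lists, and only that of hypoxia did so under both kinds of matching.

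**Figure D2:**
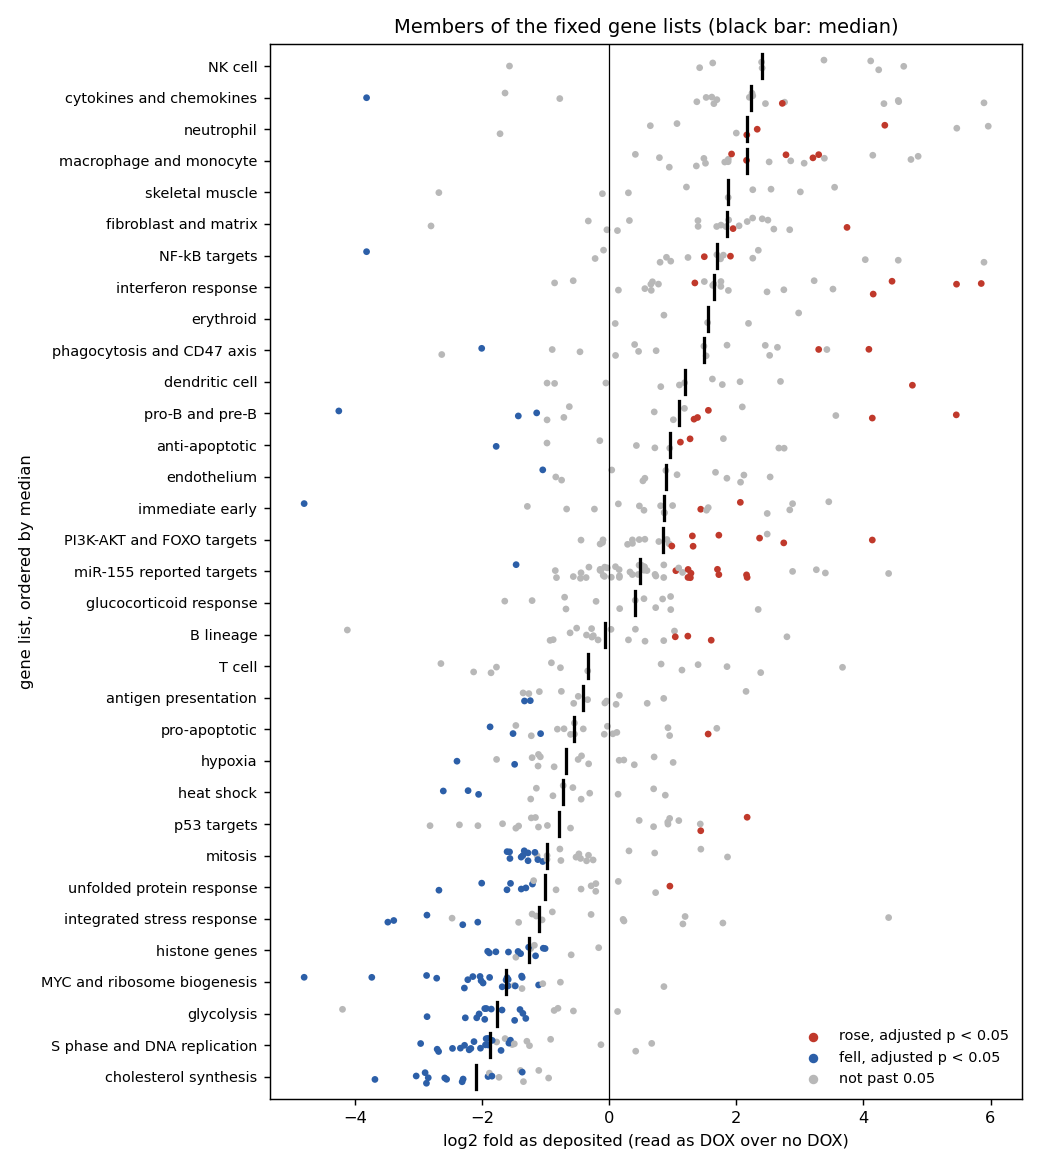
Log2 fold, read as DOX over no DOX (horizontal), of each member with a finite fold in the lists with at least 5 such members (vertical), from the authors' deposited table. Red points rose, blue points fell, grey points did not pass 0.05, and black bars are medians, from -2.10 for cholesterol synthesis to 2.41 for NK cell markers.

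The list of PI3K-AKT and FOXO targets moved the other way, with 7 of 20 members higher and 0 lower (Fisher exact adjusted p = 0.000706), 8 adjusted over the list alone. The interleukin 7 receptor gene Il7r (4.14), the repressor gene Bcl6 (2.75), Rictor, listed as 4921505C17Rik (1.73), and Txnip (1.32) led in the authors' deposited table. The list's median of 0.85 stood at percentile 96.2 of random lists. Of 23 interferon response genes 5 rose and 0 fell (0.0475), and 6 rose adjusted over the list alone. Besides Mx1 and Rsad2 these were led by Ifit3 (4.45) and Gbp2 (1.35) in the authors' deposited table. Among finite folds alone the interferon call ended (Fisher exact adjusted p = 0.0834). Macrophage markers leaned upward in the same comparison (median 2.16), while T cell markers had a median of -0.34.

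Of 49 tested genes reported as miR-155 targets, 9 rose and 1 fell (Fisher exact adjusted p for the rises = 0.0118), and 10 and 2 adjusted over the list alone. Trp53inp1 (2.17), Csf1r (2.16), Rictor and Hbp1 (1.29) led in the authors' deposited table, and Bach1 (1.24, adjusted p = 0.0403) and Picalm (1.05, 0.0428) also rose. Csf1r is also on the macrophage list, whose markers leaned upward (median 2.16). Of the risen genes named here, Hbp1 alone has no miR-155 seed match in its annotated 3' UTR. Inpp5d, the SHIP1 phosphatase gene, had a log2 fold of -0.14 (0.870) in the authors' deposited table, so no change was detectable. Socs1 (0.51, 0.861), Cebpb (4.40, 0.399) and Jarid2 (0.73, 0.156) did not pass in the authors' deposited table. The list's median of 0.49 lay at percentile 90.6 of random lists, at 84.6 of those matched on length and GC, and at 99.9 of those matched on implied spread. Implied spread is built from fold and p, so the last percentile is limited support. Members shared with other lists carried part of the call, which ended without them (0.150).

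Of 1704 genes with a miR-155 seed match in the 3' UTR, 10.5% rose and 4.69% fell, against 4.75% and 8.28% of 10915 without one. With 3' UTR length and implied spread matched, the median log2 fold of the 1545 genes with a match and an implied spread was 0.234 above that of random genes, at percentile 100. With 3' UTR length and GC matched instead, over all 1704 genes with a match, the difference was 0.102, at percentile 99.8. Under the first matching, of 6 shuffled 7-mers treated alike, 4 also lay above the central 95% of random sets, and their differences spanned 0.0869 to 0.221, against 0.219 for AGCATTA and 0.260 for GCATTAA. In a scan of 15746 7-mers adjusted for length and GC, chosen after the data were seen, AGCATTA ranked 167 and GCATTAA 173 by z score, and the shuffled 7-mers from 1136 to 13292.

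Among lymphoid genes, the pro-B and pre-B list held changes in both directions, with 5 of 16 higher and 3 lower (Fisher exact adjusted p for the rises = 0.0118), 6 and 4 adjusted over the list alone. Rag1, Il7r and Myb (1.34) rose and Kit fell in the authors' deposited table. Outside the naming rule, the other rises were Bach2 (1.56) and Sox4 (1.39) in the authors' deposited table. The other falls were Vpreb2 (-1.43) and Igll1 (-1.14) in the authors' deposited table. For the falls the list did not pass (Fisher exact adjusted p = 0.257). Of 20 B lineage genes 3 rose and 0 fell, 3 adjusted over the list alone (list 0.412): Ebf1 (1.61), Cd72 (1.24) and Blnk (1.04) in the authors' deposited table. Of 14 T cell markers 0 rose and 0 fell, also adjusted over the list alone, and their median was -0.34.

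Markers of myeloid and stromal cells leaned upward, though few passed gene by gene. All 21 tested macrophage and monocyte markers had a fold above 1 and 5 rose (Fisher exact adjusted p = 0.0342), 8 adjusted over the list alone. The efferocytosis receptor gene Mertk (3.30), the chemokine receptor gene Ccr2 (2.78), Csf1r and Apoe (1.93) led in the authors' deposited table. That call ended without members shared with other lists (0.339) or among finite folds alone (0.0609). Of 14 neutrophil markers 3 rose, 5 adjusted over the list alone (list 0.203): Csf3r (4.34), Cxcr2, listed as Il8rb (2.33), and Mmp9 (2.17) in the authors' deposited table. Of 20 fibroblast and matrix genes 2 rose, 2 adjusted over the list alone (0.906), Postn (3.74) and Pdgfra (1.95) in the authors' deposited table. Siglech (4.77) was the 1 of 12 dendritic cell markers that rose, and Lpl (2.60) the 1 of 4 adipocyte markers, in the authors' deposited table, each 1 adjusted over the list alone. Of 13 endothelial markers 1 fell, Eng (-1.04) in the authors' deposited table, and 1 adjusted over the list alone. No call was made, at the table's adjustment or adjusted over the list alone, among 12 NK cell, 10 skeletal muscle, 7 erythroid and 6 skin markers. List medians were 2.16 for macrophage, 2.17 for neutrophil, 2.41 for NK cell, 1.86 for fibroblast, 1.87 for muscle, 1.55 for erythroid, 1.19 for dendritic and 0.89 for endothelial markers. Among unmatched random lists, dendritic (percentile 97.0), erythroid (95.25) and endothelial (92.7) markers lay within the central 95%. Macrophage (100), fibroblast (100), NK cell (99.98), neutrophil (99.91) and muscle (99.63) markers lay above it. Among random lists matched on implied spread, macrophage (percentile 100) and fibroblast (98.6) markers lay above the central 95%. Neutrophil (95.7), NK cell (95.5), muscle (91.9), dendritic (69.0) and endothelial (41.2) markers lay within it. With length and GC matched instead, all of the latter lay above it, at 99.97, 99.99, 99.94, 98.66 and 97.94.

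Other lists held few calls and did not pass the Fisher test. The medians of NF-kB targets (1.70), cytokines and chemokines (2.23) and phagocytosis genes (1.49) nonetheless lay above the central 95% of random lists, at percentiles 99.9, 100 and 99.8, and also under both kinds of matching. Macrophage markers, some of them shared with the phagocytosis list, leaned upward beside them (median 2.16, percentile 100). Of 19 pro-apoptotic genes 3 fell and 1 rose, as also adjusted over the list alone: Bid (-1.87), Cycs (-1.51), Bak1 (-1.08) and Bmf (1.56) in the authors' deposited table. Of 12 anti-apoptotic genes Birc2 (1.27) and Cflar (1.12) rose and Bcl2 (-1.78) fell in the authors' deposited table, 2 and 2 adjusted over the list alone. Of 21 p53 targets 2 rose, 2 adjusted over the list alone, Trp53inp1 and Btg2 (1.44) in the authors' deposited table, while the list's median was -0.79, at percentile 0.12. Of 21 NF-kB targets 2 rose and 1 fell, as also adjusted over the list alone: Tnfaip3 (1.91), Nfkb2 and Tnf (-3.82) in the authors' deposited table. Of 25 cytokine and chemokine genes Cxcl12 rose (2.72) and Tnf fell in the authors' deposited table, 1 and 0 adjusted over the list alone. Of 21 immediate early genes Jun (2.06) and Btg2 rose and Myc fell in the authors' deposited table, as also adjusted over the list alone. Stab2 (4.09) and Mertk rose and Calr fell among 18 phagocytosis genes in the authors' deposited table, as also adjusted over the list alone. Of 16 antigen presentation genes the immunoproteasome genes Psmb8 (-1.33) and Psmb9 (-1.24) fell in the authors' deposited table, 2 adjusted over the list alone. Of 14 glucocorticoid response genes 0 passed, also adjusted over the list alone, and 1 mitochondrial-encoded gene was tested and did not pass.

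Direction went with transcript length and GC, a relation looked at after the data were seen. Across 12619 genes, Spearman's rho of log2 fold was 0.285 with transcript length and -0.245 with GC, genes not being independent replicates. In the decile of shortest transcripts 18.8% fell and 0.872% rose, and in the longest 3.41% fell and 15.9% rose. All 8 lists called as fallen, and so picked by their falls in the same data, stayed below percentile 2.5 of random lists matched on length and GC. Of the 5 lists called as risen, miR-155 targets (percentile 84.6) and PI3K-AKT and FOXO targets (94.7) lay within the central 95% of such lists, though above it, at 99.93 and 99.97, with implied spread matched.

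**Figure D3:**
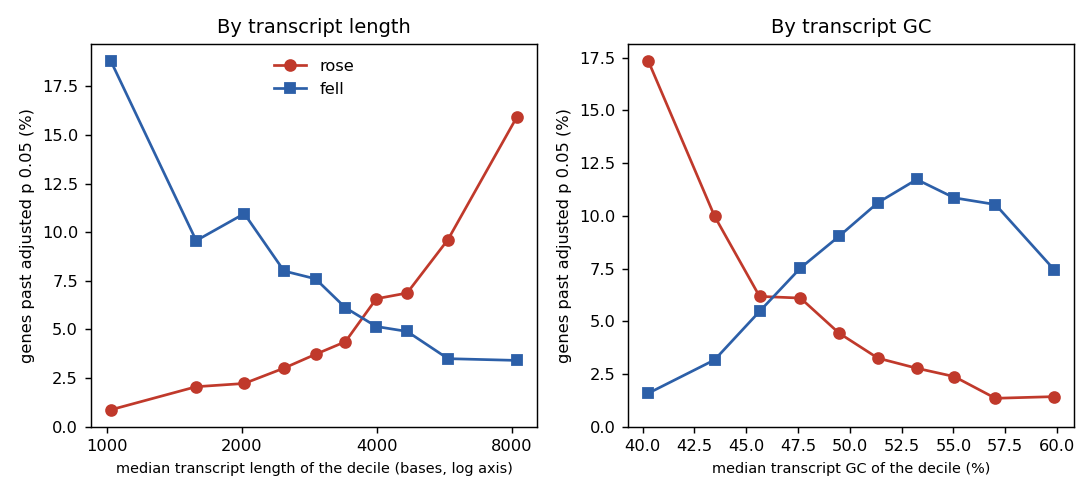
Share of genes past the authors' adjusted p of 0.05 (vertical, percent) by decile of transcript length in bases (left, log axis) and of transcript GC in percent (right), for 12619 genes. Red circles are genes that rose and blue squares genes that fell, with direction read as DOX over no DOX, and the falls drop from 18.8% to 3.41% from the shortest to the longest decile.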

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

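The restriction to finite folds, the restriction to protein-coding matches, the matching on implied spread or on length and GC, and the seed settings with 3' UTR GC or the tightest 40% of genes were chosen after seeing the data. The count of 2101 changed genes became 1145 at an adjusted p under 0.01 (576 higher, 569 lower) and 291 under Bonferroni (137 and 154), by construction stricter, and stayed within 1.5 times elsewhere, from 1808 to 2798. Of 108 called genes among the 112 named, 69 lost the call under Bonferroni and 0 when only finite folds were tested. Of 13 list calls, a threshold of 0.1 lost 1 and gained 1 (neutrophil markers, 0.0220), leaving out shared members lost 2 and finite folds alone lost 2. The cause was not tested. Among list medians, 10 lay above and 12 below the central 95% of random lists. Matching on implied spread weakened 5 (neutrophil, NK cell, muscle, pro-apoptotic and heat shock genes) and brought 3 more past it (miR-155 targets, anti-apoptotic genes, PI3K-AKT and FOXO targets), matching on length and GC 2 and 3, the mean 1 and 2, and 0 turned direction. Recentring all folds by their median of 0.17 left the p-values as they were, so it could not test the counts. The seed difference ran from 0.102 with 3' UTR length and GC matched (1704 genes) to 0.620 with implied spread matched but not length (1545 genes). No paired analysis was possible because the deposited table has no values per sample. For the same reason other tests and size factors, filters on low counts or on mean expression, pseudocounts, matching on mean expression, leaving out samples, estimated correlation and other splits of the 6 samples were not run. Depth is unknown, so whether an uncalled gene was measured well enough cannot be judged.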

Other observations

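Of the tests below, the single-exon test over all 303 genes was written before its result was seen. The gene families, the symbol scan, the 7-mer scan, the test without histones and the tests on host markers, on length and GC and on seed composition were chosen only after results had been seen.

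Further families of housekeeping genes held many falls, among them genes of translation, protein folding, protein degradation and respiration. Of 91 cytosolic ribosomal protein genes 64 fell and 0 rose (Fisher exact adjusted p = 6.40e-58), with a median log2 fold of -0.98 from the authors' deposited table. Of 45 proteasome genes 21 fell and 0 rose (2.32e-14), of 8 chaperonin genes 7 fell and 0 rose (4.37e-08), and of 39 complex I genes 14 fell and 0 rose (4.37e-08). Mitochondrial ribosomal proteins fell in 13 of 75 genes (0.000502) and translation factors in 14 of 56 (5.12e-06), where 3 rose. Each of these medians lay at or below percentile 0.2 of random lists matched on transcript length and GC. Zinc finger genes with Zfp symbols went the other way, with 32 of 269 higher and 4 lower (0.000197 for the rises). These families were picked by hand after the values were seen, which included a scan of 140 symbol stems. The adjusted p-values cover the 20 tests of such families alone, and reads of ribosomal protein genes can be shared with processed pseudogenes.

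Uncertain folds lay mostly above 1. In the decile of widest implied spread the median log2 fold was 1.51. Its 0 calls follow largely from how implied spread is built, since a wide one means a large p for a given fold. A ratio of Inf stood for 2180 tested genes, against 579 with 0. Olfactory receptor genes had an adjusted p in 3.84% of 1095 entries, against 63.5% of all entries. Of the 42 tested, 38 had a fold above 1, with a ratio of Inf in 28 and of 0 in 3. Of 2256 tested clone-named AK entries 77.8% had a fold above 1, and 171 rose and 11 fell. For comparison, 11007 of all 18543 tested genes had a fold above 1. What raised these entries was not tested.

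Markers of host cells leaned upward, with a pooled median log2 fold of 1.87 over 105 markers from 11 lists. Random lists matched on implied spread had 1.06 (percentile 100). This argues against the general upward lean as the whole source for the markers together, with the limit that implied spread is itself built from fold and p. List by list, 2 of 8 lay above the central 95%, macrophage and fibroblast, and the 9 other lists pooled stood at percentile 98.9, above the central 95% but short of the bound of 99 set for excluding the general lean, which therefore stays open for them. A lower share of tumour cells would raise the other types alike, apart from T cells, which are few in nude mice, and lysed red cells. Without these and skin, 8 lists differed (permutation p = 0.0156), but not without endothelium (0.115). The test therefore cannot tell whether a lower share of tumour cells accounts for the rise. A change within host cells of the DOX tumours stays open as well. Earlier choices of lists gave 0.000660 for all 11 and 0.0188 for 6 picked after their medians were seen.

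Rises were more frequent among long and AT-rich transcripts and falls among short ones, though most genes in each decile were not called, and falls did not climb steadily with GC (7.45% in the most GC-rich decile, 11.7% in the decile where they peaked). Length and GC as the whole cause would bring the fallen lists back among matched random lists, yet 8 of 8 stayed below percentile 2.5. These 8 were picked by their falls in the same data, so low percentiles are partly built in. The highest was 0.27, for histone genes. Matching used 5 bins of length and 5 of GC, and genes of a list are not independent. Unspliced RNA as the whole cause would leave genes with 1 exon without a length trend. Spearman's coefficient among the 303 was 0.376 (95% bootstrap 0.266 to 0.471), but 48 histone genes carried much of it, and the 255 others gave 0.160 (0.0422 to 0.275), so a part from unspliced RNA may remain. RNA quality and library preparation in the DOX samples stay open, as does a biological link of length and GC to the growth genes that fell.

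The 7mer-m8 match ranked 167 of 15746 7-mers by z score, after adjustment for length and GC of 3' UTR and transcript. Among 419 7-mers of the same bases it ranked 7, in the top 1.67%. In this scan alone, that argues against base composition of the seed shared by its shuffles as the whole source. The control with 6 shuffled 7-mers, planned in advance and not adjusted for GC, did not set this match apart. There 4 of the 6 also lay above the central 95%, and 1 had a larger difference (0.221 against 0.219). A modest rise of miR-155 targets on withdrawal is a candidate explanation, and it would go with the reading of folds as DOX over no DOX. The support is limited, since the scan was chosen after the data were seen and 6 other sequences of the same bases ranked higher. It cannot settle the order of the fold. After that adjustment the 6 shuffled 7-mers ranked from 1136 to 13292.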
